A study of Homo sapiens with 12 samples.

How the data were processed

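CD4 T cells of 24 children were profiled by CITE-seq, in which droplet-based single-cell RNA sequencing is combined with oligonucleotide-tagged antibodies, some against surface proteins and some used as hashtags that mark the child a cell came from. The children fell into 4 groups of 6 by body weight and asthma: healthy weight with asthma, obese with asthma, obese without asthma and healthy weight without asthma. Libraries 1, 2 and 3 each pooled 4 children in 1 droplet well, and library 4 pooled 12 children in 3 wells, so that each of the 6 wells held 1 child of every group. In library 4 a child was known only by its group and well, and the well therefore served as the replicate number in all comparisons.

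The values used were raw UMI counts per gene, antibody and hashtag in each cell barcode, as deposited by the authors in sparse matrices. Per the file headers the matrices came from Cell Ranger 6.0.1 for libraries 1 to 3 and Cell Ranger 7.0.1 for library 4. The submitters' processing notes name hg38 and Seurat, without a Seurat version or step. The Cell Ranger versions differ in their default handling of intronic reads and the setting used is not stated. Version and library coincide, and every library holds all 4 groups, so the library term of the models covers the version as well. The matrices held 36601 genes, of which 34616 matched a GENCODE v29 gene. Gene positions are GENCODE v29 coordinates on hg38. Genes on the Y chromosome, XIST, TSIX and the variable segments of T cell receptor and immunoglobulin genes, 678 in all, were left out of the fits.

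Barcodes were assigned to children with HTODemux in Seurat 5.3.0 at a positive quantile of 0.99, which gave 141893 singlets, 42569 doublets and 15801 barcodes without a hashtag among 200263. Singlets with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs were kept, which left 134721 cells. Scanpy 1.11.5 (leidenalg 0.10.2, igraph 0.11.9) was run on 2000 variable genes scaled within library, 30 principal components and 15 neighbours, and Leiden clustering at resolution 1.0 gave 24 clusters. Clusters were named by marker lists as naive-like, memory-like, regulatory-like or proliferating-like CD4 T cells, as another cell type, or left unnamed where no list led. Central and effector memory markers were merged into 1 class, and the cytotoxic cluster was counted among the other cell types. Both decisions, like the cluster names, were taken after the composition of each child's sample had been seen. Cells in clusters of other types were left out of the main sums. Cells in unnamed clusters were kept in the sums over all CD4 cells, whatever their CD4 antibody level. The main sums held 121087 cells and 970054856 UMIs, with 1059 to 8378 cells and 8185218 to 71508536 UMIs per child. Regulatory-like sums were the shallowest, at 471895 to 4822129 UMIs and no fewer than 66 cells per child.

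Counts were summed per child, since cells of a child are not replicates. Sums over all CD4 cells and within naive-like, memory-like and regulatory-like cells were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit, TMM scaling, filterByExpr) with group and library as terms and all 24 children in 1 fit. A class sum needed at least 50 cells, which all children had in these 3 classes. Proliferating-like cells were too few for a fit. Over 7513 genes, deviations of log2 CPM from the group mean, with library not removed, were compared between children of different groups. They correlated at 0.884 on average within a well, at 0.856 within a library but another well, and at -0.435 between libraries. These values largely reflect library and do not measure an effect of wells beyond the library term. Library was the planned term, and the well as a block was an alternative. There were 6 contrasts: obese asthma against each of the other groups, asthma against no asthma at healthy weight, obesity against healthy weight without asthma, and the interaction of obesity and asthma. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The fits tested 18674 genes in all CD4 cells, 16605 in naive-like, 14980 in memory-like and 11472 in regulatory-like cells, with biological coefficients of variation of 0.236, 0.209, 0.194 and 0.168 and 17 residual degrees of freedom. The procedure was tested on simulated data: counts were drawn around each library's mean with the fitted dispersions, and 200 genes were changed in the obese asthma group. The changed genes were taken only from those with an average log2 CPM of at least 3. Genes were drawn independently and without well effects, so the rates may not hold for the real data or for genes of lower level. Compared with obese children without asthma, in all CD4 cells the procedure called 87.5% of genes raised 1.5-fold and 95.0% of genes raised 2-fold, and 4.69% of its calls were false. In regulatory-like cells it called 50% and 95.0%, and 3.05% of its calls were false.

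A total of 30 gene lists were fixed, among them naive and quiescence, memory and activation, regulatory T cell, Th1, Th2, Th17, Tfh, cytotoxic, T cell receptor signalling, NF-kB and TNF response, type I interferon response, immediate early genes, heat shock and unfolded protein, insulin and adipokine signalling, PI3K and mTOR, glycolysis, nuclear-coded oxidative phosphorylation, mitochondrially coded transcripts, cholesterol and lipid, glucocorticoid response, chemotaxis and adhesion, asthma association, cytosolic ribosomal proteins, and markers of B and plasma cells, CD8 T cells, NK cells, monocytes, platelets and erythrocytes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and adjusted over the 30 lists. Camera with a correlation estimated per list and fry were the alternatives. Beside each list, genes were also counted with p values adjusted over the list alone. Named genes were the 10 higher and 10 lower genes with the largest change among those passing with an average log2 CPM of at least 3. Where fewer passed, the genes of smallest unadjusted p filled the 20 places for the comparisons of obese asthma with each other group. For other contrasts and for classes up to 3 passing genes in each direction were named. Genes always given included CDC42, RHOA, TBX21, GATA3, FOXP3, CCR7, GZMB, FKBP5 and NFKBIA, and up to 4 members of each list could be named. Results of 1 list and 1 gene of the rule are not reported here, though counts of lists include that list. The lists, this rule, the groups, the contrasts, the tests and most alternatives were fixed before the data were examined.

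Class shares were computed as percentages of a child's cells in the main sums. Shares and antibody levels were compared with two-sided exact permutation tests over all 924 splits of the 12 children of 2 groups, whose smallest possible p is 0.00217, and adjusted with Benjamini-Hochberg within each contrast. The 7 surface antibodies (CCR6, CCR4, CXCR3, CCR10, CD25, CD127 and CD4) were transformed to centred log-ratios per cell, averaged per child and centred within library. Alternatives for shares and antibodies were sign-flip permutations over the 6 wells, whose smallest possible p is 0.0312, and permutation within library. List levels per child are means of log2(CPM + 1) from raw UMI totals, centred within library. The 924 splits ignore library, so for values centred within library these permutation tests are approximate. Analyses in Python 3.11.15 used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

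The other alternatives were RLE size factors, no filter on low counts, no library term, the well as a block in place of library, DESeq2 1.42.0, only the groups of a contrast, a top-hashtag rule (at least 70% of at least 10 hashtag counts), at least 1000 UMIs, all singlets kept, Leiden resolution 0.5 and leaving out each well in turn. Chosen after the data were seen were a threshold on the CD4 antibody per well in place of clusters, leaving out the highest 10% of Scrublet scores, leaving out 1 child whose sample was mostly of other cell types, and the lists within classes.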

Results

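Each of the 6 wells gave 212370655 to 386074768 gene-expression UMIs, with a median of 6036 to 9109 UMIs per barcode, and 19.5% to 24.3% of barcodes carried hashtags of more than 1 child. Median UMIs per cell lay between 7212 and 7520 in the 4 groups and did not differ between them in exact permutation tests (smallest p = 0.578, n = 6 children per group). In what follows, gene levels are TMM-scaled CPM given as mean ± SD of 6 children, and log2 fold changes are given ± SE from the edgeR fit.

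Clusters separated 71426 naive-like cells, named by a list with CCR7 and LEF1, and 35375 memory-like cells, named by lists with S100A4 and ITGB1. They also separated 8285 regulatory-like cells, marked by FOXP3 and IL2RA, and 393 proliferating-like cells, marked by MKI67. Among naive-like clusters, 1 of 9010 cells came to 96.6% from a single well. Another, of 10854 cells, had only 3 genes of the naive marker list raised. Clusters of other types, among them B cells, CD8 T cells, NK-like cytotoxic cells, monocytes, dendritic cells and a cluster led by platelet genes, held 13634 cells. They made up 5.13% ± 1.47 of the cells of children with asthma at healthy weight and 14.4% ± 8.23 in obese asthma. In the groups without asthma they made up 8.04% ± 3.48 in obesity and 18.6% ± 28.3 at healthy weight. Without the child of library 1 the last value was 7.05% ± 1.91. The share of other types was higher in obese asthma than in healthy-weight asthma by 9.23 points in 5 of 6 wells (exact permutation p = 0.0130, adjusted p = 0.0520). This test was not among the planned tests of class shares. Its p value was adjusted with those of the cytotoxic share of CD4 antibody-positive cells, the share of 1 naive-like cluster and median UMIs per cell. Cells in the cytotoxic cluster, which expresses granzymes and NK receptors, made up 1.70% ± 1.26 in healthy-weight asthma and 6.58% ± 5.60 in obese asthma, and 3.47% ± 2.01 in obesity and 6.63% ± 9.23 at healthy weight without asthma. Without the highest child of each group, that of library 2 in obese asthma (16.8%) and that of library 1 at healthy weight without asthma (25.3%), the means were 1.25%, 4.54%, 2.78% and 2.90%, an omission chosen after the values were seen. Clusters that no marker list named held 3.70% ± 1.63 of the retained cells in healthy-weight asthma, 5.65% ± 4.10 in obese asthma, 4.55% ± 2.15 in obesity without asthma and 5.85% ± 4.45 at healthy weight without asthma. These were 3 clusters: 1 of low UMI count, 1 led by ZBTB16, KLRB1 and TRDC, and 1 led by SPINK2 and PRSS57. Above the CD4 antibody threshold lay 95.4% of cells in the first and 20.7% in the last. The share in the ZBTB16 cluster was close to the 49.9% of the cytotoxic cluster, which was left out. Sums and shares of all CD4 cells thus include some cells below that threshold. They also leave out some above it, among them 83.2% of the 512 cells in the cluster led by platelet genes. The effect of the 3 unnamed clusters alone on KLRB1 and Th17 genes in these sums was not tested.

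Naive-like cells made up 48.1% ± 20.9 of CD4 cells in obese asthma, 57.6% ± 16.5 in obesity without asthma, 62.9% ± 5.35 in healthy-weight asthma and 53.3% ± 15.7 at healthy weight without asthma. Memory-like cells made up 36.7% ± 17.9, 31.3% ± 13.4, 25.7% ± 3.18 and 34.7% ± 16.2 in the same order. In obese asthma the naive-like share was lower than in obesity without asthma in 6 of 6 wells. The mean difference of -9.49 points was within the spread between children (exact permutation p = 0.409). The memory-like share was higher in 6 of 6 wells, by 5.42 points (exact permutation p = 0.561). With wells as blocks, exact sign-flip permutations gave p = 0.0312 for each of these differences, the smallest they can give, and adjusted p = 0.0625. With only these classes at that floor, neither could pass after adjustment. Against healthy-weight asthma the naive-like share differed by -14.8 points (p = 0.108) and the memory-like share by 11.04 points (p = 0.173, both exact permutation tests). These were -9.32 and 6.69 points without well 2. With the top-hashtag rule, which kept 33.7% of the singlets of well 2, they were -3.52 and 1.63 points (exact permutation p = 0.771 and 0.877). In wells 1, 2 and 3 this rule moved the naive-like share of healthy-weight asthma from 69.4%, 54.4% and 59.1% to 49.0%, 18.3% and 40.2%. In obese asthma that share went from 45.3%, 12.3% and 53.0% to 43.5%, 17.2% and 36.6%. The rule thus changed shares unevenly between children, and the smaller differences do not settle the comparison. Regulatory-like cells, which restrain immune responses, made up 8.93% ± 2.80 in obese asthma and 5.70% ± 1.82 at healthy weight without asthma. That difference of 3.23 points, higher in 4 of 6 wells, had an exact permutation p of 0.0455 and an adjusted p of 0.182. The regulatory-like share was 6.01% ± 2.25 in obesity without asthma and 7.52% ± 2.82 in healthy-weight asthma. Proliferating-like cells made up 0.180% ± 0.0732 to 0.579% ± 0.767 of CD4 cells. Of 20 two-sided comparisons of the shares of the 4 classes 0 passed after adjustment, and 1 had an unadjusted p below 0.05. The share of other cell types, tested separately above, was not among them. Among 35 comparisons of the surface proteins CCR6, CCR4, CXCR3, CCR10, CD25, CD127 and CD4, 0 passed and 0 had an unadjusted p below 0.05 in exact permutation tests (smallest p = 0.180, smallest adjusted p = 0.868). The difference of greatest size was in CCR6, a homing receptor of Th17 cells, at -0.126 centred log-ratio units in healthy-weight asthma against healthy weight without asthma, lower in 6 of 6 wells. CCR6 was also lower in 6 of 6 wells in obese asthma against healthy weight without asthma (-0.0612). CCR10, a skin-homing receptor, was lower in 6 of 6 wells in obese asthma against obesity without asthma (-0.0160) and against healthy-weight asthma (-0.0596). With wells as blocks, exact sign-flip permutations gave p = 0.0312 for these 4 differences, the smallest they can give, and 0 of 35 passed (smallest adjusted p = 0.219). An antibody that alone reaches this floor in its contrast cannot pass the adjustment, so this test could not decide on these differences.

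**Figure D1:**
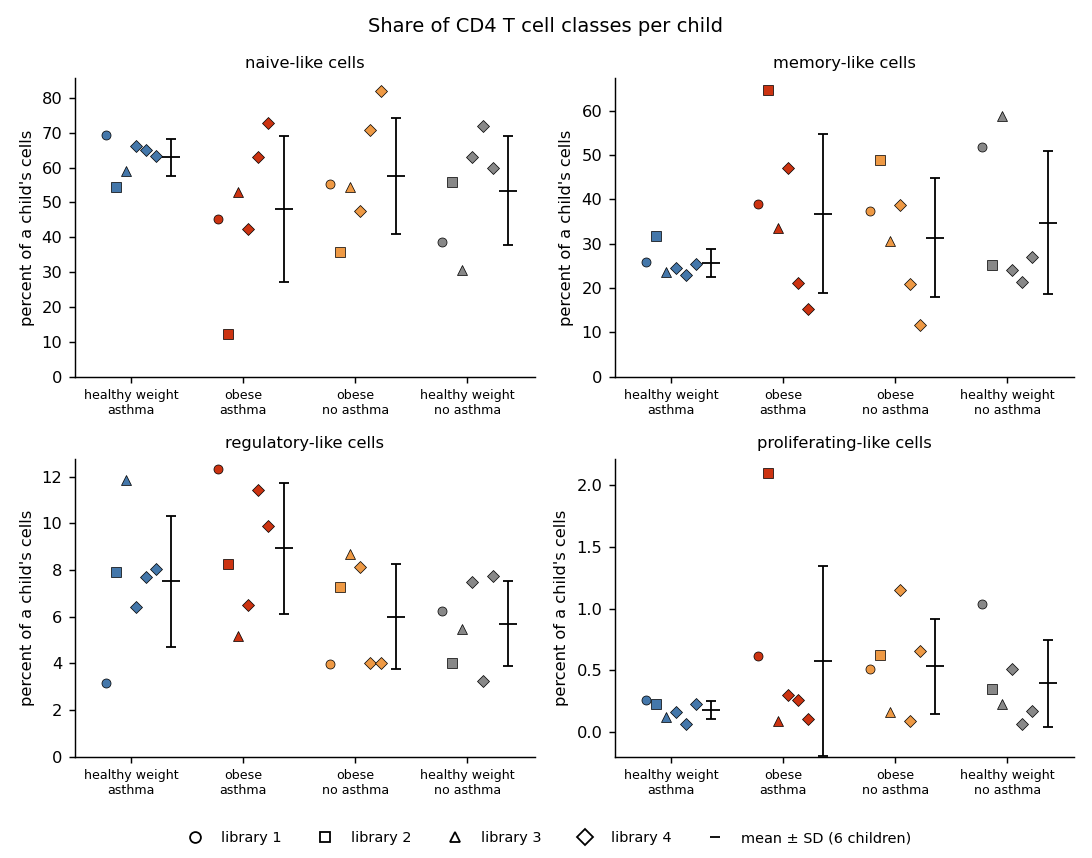
Percent of each child's CD4 cells in the naive-like, memory-like, regulatory-like and proliferating-like classes, by group; points are children, marker shapes are libraries and dashes with bars are means ± SD of 6 children. Naive-like shares averaged 48.1% in obese asthma and 62.9% in healthy-weight asthma, with wide overlap.

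Obese children with asthma were first compared with obese children without asthma. Interferon-induced antiviral genes were lower in obese asthma: MX1 (chromosome 21, 41420304 to 41459214, plus strand) was at 25.1 ± 5.19 CPM against 36.3 ± 19.1 (log2 fold change -0.45 ± 0.14, lower in 5 of 6 wells). TRIM22 (chromosome 11, 5689689 to 5737089, plus strand) was at 57.1 ± 19.9 against 72.1 ± 32.6 (-0.30 ± 0.10, lower in 6 of 6 wells). RSAD2 and IFI44, from the same response, had log2 fold changes of -0.64 ± 0.23 and -0.43 ± 0.17. All 24 genes of the type I interferon list were lower, with a median log2 fold change of -0.30, and 0 passed when adjusted over the list alone. The camera test gave adjusted p = 2.09e-14 with the preset correlation and adjusted p = 0.262 with an estimated correlation. The mean level of the list per child was -0.13 ± 0.15 in obese asthma and 0.18 ± 0.24 in obesity without asthma in all CD4 cells (difference -0.31, exact permutation p = 0.0152, lower in 5 of 6 wells). The same difference was -0.36 in naive-like cells (exact p = 0.00433, adjusted p = 0.0130, lower in 6 of 6 wells). It was -0.34 in memory-like cells (exact p = 0.00649, adjusted p = 0.0130, 5 of 6 wells) and -0.37 in regulatory-like cells (exact p = 0.0108, adjusted p = 0.0144, 5 of 6 wells). These tests per child were chosen after the list result was seen. Their p values were adjusted over all CD4 cells and the classes for this list alone, not over the 30 lists. In all CD4 cells healthy-weight children had intermediate levels, and obese asthma differed from them by -0.10 with asthma (exact permutation p = 0.474) and by -0.11 without (p = 0.375). In regulatory-like cells the level in healthy-weight asthma, -0.15, was below that in obese asthma, -0.10.

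**Figure D2:**
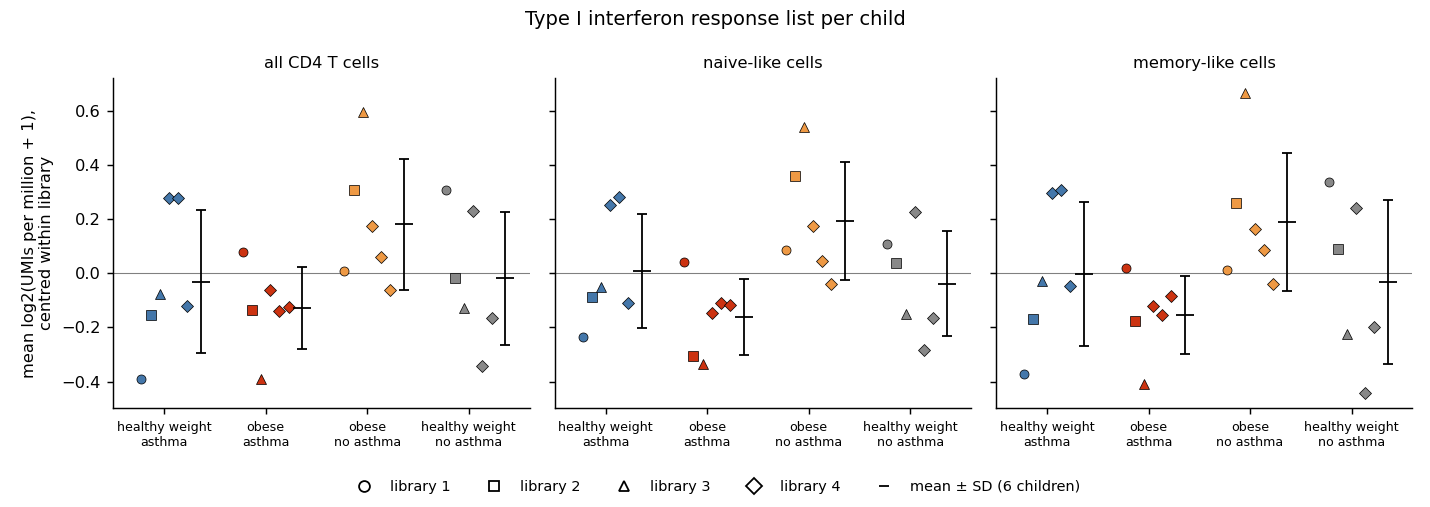
Mean log2(CPM + 1) of the type I interferon response genes per child, centred within library, in all CD4, naive-like and memory-like cells, by group; points are children, marker shapes are libraries and dashes with bars are means ± SD of 6 children. In all CD4 cells obese asthma averaged -0.13 and obesity without asthma 0.18.

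Th2 genes, which drive allergic inflammation, were higher in obese asthma than in obesity without asthma. The Th2 master regulator GATA3 (chromosome 10, 8045378 to 8075203, plus strand) was at 70.2 ± 23.8 CPM against 47.3 ± 16.99 (log2 fold change 0.56 ± 0.19, higher in 6 of 6 wells). The IL-25 receptor gene IL17RB and the chemokine receptor gene CCR3 had log2 fold changes of 1.51 ± 0.50 and 1.54 ± 0.67. Of the Th2 list 10 of 12 genes were higher (median 0.65), with 2 passing when adjusted over the list alone, GATA3 and IL17RB (camera adjusted p = 4.07e-06 and adjusted p = 0.262 with an estimated correlation). Follicular helper genes, which serve help to B cells, were lower for 9 of 12 genes (median -0.25), among them PDCD1 at -1.05 ± 0.41, TOX2 at -0.70 ± 0.32 and IL21 at -1.31 ± 0.61 (camera adjusted p = 0.00103 and adjusted p = 0.262 with an estimated correlation). The naive-cell homing receptor CCR7 (chromosome 17, 40553769 to 40565472, minus strand) was at 155 ± 43.3 CPM in obese asthma and 198 ± 40.6 in obesity without asthma (-0.35 ± 0.13, lower in 5 of 6 wells). The naive list was lower for 10 of 16 genes (camera adjusted p = 0.0191 and adjusted p = 0.722 with an estimated correlation), while the naive-like share was lower and the memory-like share higher in 6 of 6 wells. The median of the list was -0.04 in all CD4 cells, 0.04 within naive-like cells and -0.04 within memory-like cells. Immediate early genes were higher for 23 of 23 genes (adjusted p = 9.19e-04 and adjusted p = 0.722 with an estimated correlation). So were memory genes for 16 of 20 (median 0.18 in all CD4 cells, 0.08 within naive-like and 0.04 within memory-like cells), regulatory T cell genes for 10 of 13 and mitochondrially coded transcripts for 12 of 13 (for each of the 3 adjusted p = 0.00256 and adjusted p = 0.722 with an estimated correlation). Asthma association genes were higher for 12 of 18 genes (adjusted p = 0.00256 and adjusted p = 0.262 with an estimated correlation). Nuclear-coded oxidative phosphorylation genes were lower for 31 of 34 genes with a median of only -0.05 (adjusted p = 0.00973 and adjusted p = 0.884 with an estimated correlation; 0.0548 with RLE scaling). Apart from Th2, these lists had 0 genes passing when adjusted over the list alone.

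Among genes of an average log2 CPM of at least 3, the smallest p value in this comparison belonged to MRPS18B, a mitochondrial ribosomal protein gene (chromosome 6, 30617709 to 30626395, plus strand). It was at 17.1 ± 4.79 CPM in obese asthma against 22.4 ± 4.19 (log2 fold change -0.42 ± 0.10, lower in 6 of 6 wells). POU2F2, a lymphocyte transcription factor gene, was at 27.7 ± 5.38 against 21.2 ± 5.86 (0.42 ± 0.11, higher in 6 of 6 wells). PIK3IP1, an inhibitor of PI3K signalling in T cells (chromosome 22, 31281593 to 31292534, minus strand), was at 258 ± 66.3 against 320 ± 55.9 CPM (-0.32 ± 0.09, lower in 6 of 6 wells). The interferon-related genes EIF2AK2 and PLSCR1 had log2 fold changes of -0.35 ± 0.11 and -0.59 ± 0.19, and HSH2D, PHF21A and MINK1 had -0.35 ± 0.10, 0.35 ± 0.10 and 0.48 ± 0.15. The others filling the list were lower for ABHD15-AS1, MRTO4, VMAC, TM2D2, TMEM33 and ZNF273 and higher for GPR108, GDAP1, GIPC1 and TMEM65. None of these genes passed: edgeR called 0 of 18674 genes (smallest adjusted p = 1.00), 621 had an unadjusted p below 0.05, and DESeq2 called 0. Other splits of the children within libraries gave more genes at an unadjusted p below 0.05 in each contrast over all CD4 cells. Such counts alone therefore do not tell signal from chance.

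Obese children with asthma were next compared with healthy-weight children with asthma. Activation and memory genes were higher in obese asthma: CD69, an early activation marker, at a log2 fold change of 0.72 ± 0.20, AHNAK at 0.66 ± 0.19 and S100A4 at 0.79 ± 0.23. The memory list was higher for 19 of 20 genes (median 0.55), with 7 passing when adjusted over the list alone (camera adjusted p = 3.11e-11 and adjusted p = 0.239 with an estimated correlation). Immediate early genes were higher for 23 of 23 genes (median 0.41), including IER2, DUSP2 and BTG2, with CD69 passing when adjusted over the list alone (adjusted p = 2.23e-09 and adjusted p = 0.279 with an estimated correlation). NF-kB and TNF response genes were higher for 18 of 20 genes (median 0.30), with LTA at 0.36 ± 0.11 and CD83 at 0.52 ± 0.18 (adjusted p = 1.87e-07 and adjusted p = 0.239 with an estimated correlation). Glycolysis genes were higher for 20 of 21 genes, among them the glucose transporter gene SLC2A1 at 0.39 (adjusted p = 3.28e-05 and adjusted p = 0.239 with an estimated correlation). Naive genes were lower for 14 of 16 genes (camera adjusted p = 4.92e-05 and adjusted p = 0.279 with an estimated correlation). Of these, IL7R at -0.38 ± 0.12, BACH2 at -0.46 ± 0.16, ACTN1 at -0.43 ± 0.15 and CCR7 at -0.35 ± 0.13 passed when adjusted over the list alone. Sums over all CD4 cells mix classes, and the memory-like share was 36.7% against 25.7% and the naive-like share 48.1% against 62.9% in these groups. These differences shrank to 1.63 and -3.52 points with the top-hashtag rule, which changed shares unevenly between children. Within memory-like cells the median log2 fold change of memory genes was 0.25 and within naive-like cells 0.08, against 0.55 in all CD4 cells. Naive genes had a median of -0.09 within memory-like cells and of 0.00 within naive-like cells.

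Genes of effector subsets were also higher in obese asthma than in healthy-weight asthma. Cells of other types, left out of these sums, made up 14.4% against 5.13% of cells, and the cytotoxic cluster among them 6.58% against 1.70%. Cytotoxic genes were higher for 17 of 18 genes, with NKG7 at 0.95 ± 0.42 (adjusted p = 5.93e-04 and adjusted p = 0.279 with an estimated correlation). Their median was 0.46 in all CD4 cells and 0.32 within memory-like cells, where the list did not pass (adjusted p = 0.0648). Th17 genes were higher for 12 of 13, with BATF at 0.66 and KLRB1 at 0.72 (adjusted p = 5.93e-04 and adjusted p = 0.264 with an estimated correlation). Th2 genes were higher for 11 of 12 genes, with GATA3 at 0.49 ± 0.19 in 5 of 6 wells (adjusted p = 0.00112 and adjusted p = 0.279 with an estimated correlation). Th1 genes were higher for 12 of 15, with RUNX3 at 0.40 (adjusted p = 0.00233 and adjusted p = 0.289 with an estimated correlation). NK cell genes were higher for 8 of 10 genes, with the chemokine gene XCL1 at 1.63 ± 0.49 passing when adjusted over the list alone (adjusted p = 0.00357 and adjusted p = 0.279 with an estimated correlation). Asthma association genes (adjusted p = 0.00233, and 0.239 with an estimated correlation), regulatory T cell genes (0.00440 and 0.329), insulin and adipokine genes (0.0132 and 0.277) and platelet genes (0.0176 and 0.279) were higher too. Glucocorticoid response genes as a list did not pass (adjusted p = 0.380), though PIK3IP1 and SMAP2, at -0.44 ± 0.09 and -0.42 ± 0.13, passed when adjusted over the list alone.

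Among genes of an average log2 CPM of at least 3, the smallest p value against healthy-weight asthma belonged to MRPL49, a mitochondrial ribosomal protein gene. MRPL49 (chromosome 11, 65122183 to 65127371, plus strand) was at 17.5 ± 3.85 CPM in obese asthma against 25.7 ± 8.19 (log2 fold change -0.55 ± 0.11). MRPS26 was at 24.8 ± 7.46 against 33.4 ± 10.8 (-0.43 ± 0.10), both lower in 6 of 6 wells. MRPS18B, IMP3 and TRMU, which serve translation or its RNAs, had log2 fold changes of -0.42 ± 0.10, -0.53 ± 0.11 and -0.49 ± 0.11, and PIK3IP1 was lower in 5 of 6 wells. EZH2, a histone methyltransferase gene (chromosome 7, 148807383 to 148884321, minus strand), was at 34.0 ± 11.01 CPM against 22.8 ± 6.13 (0.57 ± 0.13). ANKRD28 had 0.50 ± 0.12 and C1GALT1, a glycosyltransferase gene, 0.32 ± 0.07, and all 3 were higher in 6 of 6 wells. The rest were lower: ZNF273, OBI1, CDC37L1, TMEM223, VMAC, THAP7, HSD17B7, TEX30, BET1L, TM2D2 and TSHZ1. The 20 genes had adjusted p = 0.228 in edgeR, which called 0 genes (smallest adjusted p = 0.133) with 1628 at an unadjusted p below 0.05, and DESeq2 called 43, 16 higher and 27 lower. With the well as block edgeR called 1 gene, ZNHIT2 (-0.72 ± 0.11), and without well 6 it called 3, ZNHIT2, CADM1 and an HLA gene, all named after their values were seen.

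Obese children with asthma were then compared with healthy-weight children without asthma. Mitochondrially coded transcripts, which encode subunits of the respiratory chain, were higher in obese asthma: MT-ND5 at a log2 fold change of 0.35 ± 0.12 and MT-CO3 at 0.32 ± 0.13. Of the list 12 of 13 genes were higher, with a median of 0.28 (camera adjusted p = 7.16e-07 and adjusted p = 0.857 with an estimated correlation). CEBPB, an inflammatory transcription factor gene (chromosome 20, 50190734 to 50192689, plus strand), was at 54.7 ± 21.5 CPM against 77.7 ± 26.7 (-0.51 ± 0.12). The histone deacetylase gene HDAC4 (chromosome 2, 239048168 to 239401654, minus strand) was at 23.3 ± 15.1 against 35.1 ± 24.3 (-0.51 ± 0.11). ITPKB, a kinase gene of T cell receptor signalling, was at 111 ± 40.3 against 160 ± 70.3 (-0.51 ± 0.14), and all 3 were lower in 6 of 6 wells. PHF21A, a chromatin reader gene (chromosome 11, 45929323 to 46121178, minus strand), was at 27.5 ± 12.9 against 19.3 ± 7.89 CPM (0.48 ± 0.10, higher in 6 of 6 wells), and L3MBTL3 had 0.54 ± 0.14. These did not pass: edgeR gave adjusted p = 0.376 for PHF21A and HDAC4 and 0.392 for CEBPB. The other genes filling the list were GDAP1 and SENP1, higher, and LINC02649, KIAA1958, ABHD15-AS1, BET1L, PTTG1IP, MRPS18B, TSHZ1, PIK3IP1, ZHX2, SLA, CES2, ZFPM1 and ITPKB-AS1, lower. In all CD4 cells edgeR called 0 genes (smallest adjusted p = 0.227), 1075 had an unadjusted p below 0.05, and DESeq2 called 4: PHF21A higher and EXTL3, FZD1 and LINC02649 lower, of which EXTL3 and FZD1 were named after their values were seen.

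Lower lists in the same comparison were naive, glucocorticoid response and follicular helper genes (adjusted p = 0.0343 each), interferon response (0.0382) and heat shock genes (0.0464), each at adjusted p = 0.857 with an estimated correlation. They included the follicular helper gene CD200 at -0.59 ± 0.18 and the glucocorticoid-induced gene PIK3IP1 at -0.32 ± 0.09, which passed when adjusted over the list alone, and PDCD1 at -0.94 ± 0.41, MX1 at -0.37 and HSPH1 at -0.38, which did not. The CD8 T cell list did not pass (adjusted p = 0.116), but CD8A at -2.17 ± 0.77 passed when adjusted over the list alone. Without the child at healthy weight without asthma in library 1, whose sample was mostly other cell types, the interferon, follicular helper and glucocorticoid lists did not pass (adjusted p = 0.613, 0.0707 and 0.199).

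At healthy weight, children with asthma were compared with children without. Th17 genes, of a subset tied to neutrophilic inflammation, were lower with asthma for 13 of 13 genes (median -0.65): IL1R1 at -1.06 ± 0.35, CCL20 at -1.46 ± 0.51 and KLRB1 at -0.85 ± 0.35 (camera adjusted p = 2.08e-08 and adjusted p = 0.0752 with an estimated correlation). Cytotoxic genes were lower for 17 of 18 genes, with NKG7 at -1.22 ± 0.43 (adjusted p = 4.90e-08 and adjusted p = 0.214 with an estimated correlation). Memory genes were lower for 18 of 20, with VIM at -0.56 ± 0.18 (adjusted p = 2.48e-08 and adjusted p = 0.226 with an estimated correlation). The memory-like share was 25.7% with asthma against 34.7% without, and the naive-like share 62.9% against 53.3%. The median of memory genes was -0.44 in all CD4 cells, -0.32 within memory-like and -0.14 within naive-like cells. Glucocorticoid response genes were lower for 15 of 19 genes, and DDIT4 at -0.98 ± 0.26, SGK1 at -0.96 ± 0.30 and CEBPD at -0.81 ± 0.27 passed when adjusted over the list alone (adjusted p = 3.59e-04 and adjusted p = 0.284 with an estimated correlation). The adipokine gene RETN, at -1.99 ± 0.49, passed when adjusted over its list alone (insulin and adipokine genes, adjusted p = 6.99e-04 and adjusted p = 0.193 with an estimated correlation). CD8 T cell genes were lower, with CD8A at -2.61 ± 0.75 (adjusted p = 0.0181 and adjusted p = 0.308 with an estimated correlation). Also lower were immediate early genes (3.34e-07 and 0.308), NF-kB and TNF genes (2.35e-06 and 0.216), Th1 genes (2.30e-05 and 0.226), and glycolysis genes (3.27e-05 and 0.216), given as adjusted p with the preset and with an estimated correlation. In the same terms, heat shock (6.99e-04 and 0.426), NK cell (8.05e-04 and 0.239), chemotaxis and adhesion (0.00613 and 0.371), asthma association (0.0236 and 0.294), cholesterol and lipid (0.0297 and 0.426) and platelet genes (0.0297 and 0.345) were lower. Mitochondrially coded transcripts were higher (0.00446 and 0.427). In all CD4 cells edgeR called 0 genes (smallest adjusted p = 0.710), 1299 had an unadjusted p below 0.05 and DESeq2 called 0. Without the child of library 1 in the group without asthma, the asthma association, CD8, NK cell and platelet lists did not pass (adjusted p = 0.0975, 0.342, 0.213 and 0.0596). Monocytes, left out of the sums, were 16.9% of that child's cells, against at most 1.40% in the other 23 children. Values of single genes such as RETN without that child are not given here.

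Without asthma, obese children were compared with children at healthy weight. Interferon response genes were higher in obesity for 20 of 24 genes (median 0.26), with TRIM22 at 0.30 ± 0.10 and LY6E at 0.30 ± 0.12 (camera adjusted p = 3.19e-05 and adjusted p = 0.687 with an estimated correlation). The level of the list per child differed by 0.20 (exact permutation p = 0.182, n = 6). Oxidative phosphorylation genes were higher for 32 of 34 genes with a median of 0.07 (adjusted p = 0.00153), and mitochondrially coded transcripts for 12 of 13 (adjusted p = 0.0257), both at adjusted p = 0.687 with an estimated correlation. Cytotoxic genes were lower for 16 of 18 genes (adjusted p = 0.00620), and CD8A at -1.93 ± 0.72 and CD8B at -1.48 ± 0.55 passed when adjusted over the CD8 list alone (list adjusted p = 0.00664). Both lists had adjusted p = 0.687 with an estimated correlation. Th1, Th2, Th17, insulin and adipokine and glucocorticoid response genes were lower at adjusted p = 0.0405 each, and each had adjusted p = 0.687 with an estimated correlation. Without the healthy-weight child of library 1, only the interferon and oxidative phosphorylation lists of the 10 named here still passed, and the cytotoxic list then had adjusted p = 0.969. The heat shock and ribosomal protein lists passed in addition (adjusted p = 0.0330 and 0.0124). In all CD4 cells edgeR called 0 genes (smallest adjusted p = 1.00), 619 had an unadjusted p below 0.05 and DESeq2 called 0. With the well as block edgeR called 1, AC105094.2 at a log2 fold change of 3.58, named after its values were seen.

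The interaction asked whether the effect of asthma differed between obese and healthy-weight children. GATA3 had an interaction of 1.00 ± 0.26 on the log2 scale, since it was higher with asthma in obesity and lower with asthma at healthy weight (-0.45 ± 0.19). It passed when adjusted over the Th2 list alone (list adjusted p = 8.84e-05 and adjusted p = 0.256 with an estimated correlation). Memory genes were more positive for 18 of 20 genes, with AHNAK at 0.83 ± 0.26 (adjusted p = 4.32e-09 and adjusted p = 0.221 with an estimated correlation). Immediate early genes were so for 23 of 23 (adjusted p = 4.55e-09 and adjusted p = 0.259 with an estimated correlation). RETN at 2.88 ± 0.69 passed when adjusted over the insulin and adipokine list alone (list adjusted p = 8.61e-04 and adjusted p = 0.212 with an estimated correlation). Interferon response genes were more negative for 20 of 24 genes (5.53e-05 and 0.293), as were naive genes for 15 of 16 (0.00380 and 0.406), given as adjusted p with the preset and with an estimated correlation. In the same terms, NF-kB and TNF (4.05e-06 and 0.221), cytotoxic (4.05e-06 and 0.221), Th17 (4.95e-05 and 0.212), Th1 (1.42e-04 and 0.259), asthma association (4.15e-04 and 0.212), and glycolysis genes (0.00144 and 0.259) were more positive. So were regulatory T cell (0.00189 and 0.293), NK cell (0.00285 and 0.259), CD8 T cell (0.0215 and 0.293), glucocorticoid (0.0295 and 0.475) and heat shock genes (0.0445 and 0.657). In all CD4 cells edgeR called 0 genes (smallest adjusted p = 0.291), 1221 had an unadjusted p below 0.05, and DESeq2 called 3, CADM1, PPP1R2C and RALGPS1, named after their values were seen. Without the healthy-weight child without asthma of library 1 the glucocorticoid, CD8 and NK cell lists did not pass (adjusted p = 0.109, 0.236 and 0.149). The interaction of RETN without that child is not given here.

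In regulatory-like cells, KLRB1, which encodes the lectin-like receptor CD161 of cells with Th17 traits (chromosome 12, 9594551 to 9607886, minus strand), was higher in obese asthma than in obesity without asthma or healthy-weight asthma. Its level was 148 ± 47.1 CPM of raw UMI totals in obese asthma, 64.3 ± 16.6 in obesity without asthma, 66.8 ± 24.2 in healthy-weight asthma and 112 ± 37.0 at healthy weight without asthma (n = 6 children each). The log2 fold change was 1.22 ± 0.19 against obesity without asthma (edgeR adjusted p = 0.0236) and 1.22 ± 0.19 against healthy-weight asthma (adjusted p = 0.00965), each higher in 6 of 6 wells. Against healthy weight without asthma it was 0.45 ± 0.19 (adjusted p = 0.652, higher in 5 of 6 wells), and ranged from 0.16 without well 5 to 0.64 without well 3. The interaction was 2.00 ± 0.28 (adjusted p = 0.00281), as KLRB1 was at -0.78 ± 0.20 with asthma at healthy weight, lower in 6 of 6 wells but not past the threshold (adjusted p = 0.321). In obesity without asthma it was likewise at -0.78 ± 0.20 against healthy weight without asthma, lower in 6 of 6 wells (edgeR adjusted p = 1.00). Exact permutation tests of KLRB1 per child, chosen after the result was seen, were adjusted over overlapping parts of the CD4 cells and not over genes. Tests of its level depended on the scale. On log2 values centred within library they gave exact permutation p = 0.00649 for obesity without asthma (-0.75, adjusted p = 0.0390) and p = 0.00866 for asthma at healthy weight (-0.73, adjusted p = 0.0520). On CPM of raw UMI totals neither passed (-47.9 and -45.4 CPM, exact permutation p = 0.0216 and 0.0390, adjusted p = 0.0736 and 0.188). The contrasts of obese asthma that passed were thus against the 2 groups with the lowest levels. A KLRB1 UMI was seen in 23.8% ± 4.97 of regulatory-like cells in obese asthma and 14.8% ± 2.58 in obesity without asthma (exact permutation p = 0.00217, the smallest it can give, adjusted p = 0.0130, n = 6). Naive-like cells, at a median of 6814 to 7557 UMIs per cell against 6340 to 6664 in regulatory-like cells, gave 5.98% to 7.11% across groups. In memory-like cells KLRB1 was at 379 ± 70.02 CPM in obese asthma and 354 ± 68.9 in obesity without asthma. The call against obesity without asthma was lost with the well as block (1.22 ± 0.20, adjusted p = 0.114). It was also lost without well 1, 2, 4 or 6 (log2 fold changes 1.17, 1.24, 1.18 and 1.32, adjusted p = 0.349, 0.307, 0.871 and 0.172). Against healthy-weight asthma it was lost without well 2, 4 or 6 (log2 fold changes 1.30, 1.27 and 1.25, adjusted p = 0.0718, 0.174 and 0.0747). The interaction was lost without well 1, 4 or 6 (1.97, 2.01 and 2.08, adjusted p = 0.0746, 0.0623 and 0.0513).

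**Figure D3:**
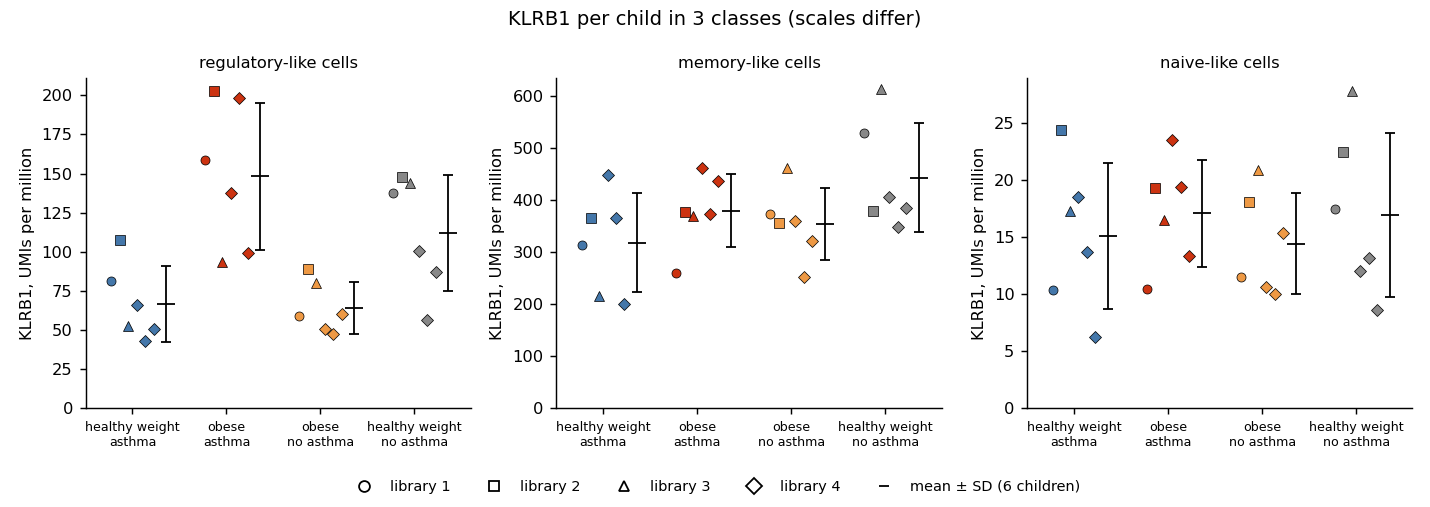
KLRB1 level in CPM of raw UMI totals in regulatory-like, memory-like and naive-like cells of each child, by group, on separate scales; points are children, marker shapes are libraries and dashes with bars are means ± SD of 6 children. In regulatory-like cells obese asthma averaged 148 and obesity without asthma 64.3.

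CDKN2D, an inhibitor of cell cycle entry (chromosome 19, 10566462 to 10569059, minus strand), was higher in regulatory-like cells of obese asthma than of healthy-weight asthma. It was at 124 ± 55.0 CPM against 70.9 ± 29.9 (log2 fold change 0.80 ± 0.13, adjusted p = 0.00965, higher in 6 of 6 wells). Against obesity without asthma, at 103 ± 44.5 CPM, its log2 fold change was 0.24 ± 0.13, and against healthy weight without asthma, at 94.1 ± 34.3 CPM, it was 0.33 ± 0.13, and neither passed (adjusted p = 1.00 and 0.606). The call against healthy-weight asthma was lost without well 2 or 4 (log2 fold changes 0.77 and 0.78, adjusted p = 0.0845 and 0.174) and at the coarser clustering (0.73, adjusted p = 0.184). In regulatory-like cells edgeR thus called 1 gene against obesity without asthma (566 at an unadjusted p below 0.05; DESeq2 1). It called 2 against healthy-weight asthma (909; DESeq2 26, 22 higher and 4 lower) and 1 in the interaction (729; DESeq2 8). Counts were 0 against healthy weight without asthma (811; DESeq2 1, TTC3-AS1), 0 for asthma at healthy weight (813; DESeq2 14) and 0 for obesity without asthma (495; DESeq2 0). With the well as block edgeR called ID2 and PDE4A for asthma at healthy weight, at -0.79 and -0.91, and KLRB1 and ID2 in the interaction. TTC3-AS1, ID2 and PDE4A were named after their values were seen.

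In naive-like cells edgeR called 0 genes in each of the 6 contrasts. At an unadjusted p below 0.05 there were 742, 1194 and 1366 for obese asthma against obesity without asthma, healthy-weight asthma and healthy weight without asthma. There were 852 for asthma at healthy weight, 694 for obesity without asthma and 857 for the interaction. DESeq2 called 12 against healthy-weight asthma, 1 against healthy weight without asthma (PTTG1IP at -0.70) and 0 elsewhere. With the well as block edgeR called TEX14 against healthy-weight asthma, IGSF11 and TRHDE for asthma at healthy weight, and AC105094.2, MKX and TRHDE for obesity without asthma. Without well 4 it called SMC1B against healthy weight without asthma, at -1.97. In memory-like cells edgeR called 0 genes in each contrast, with 546, 966, 1080, 1169, 654 and 906 at an unadjusted p below 0.05 in the same order. There DESeq2 called only PDCD1, the inhibitory receptor PD-1, in obese asthma against obesity without asthma (-1.37 ± 0.27, adjusted p = 0.00584). The genes of this paragraph were named after their values were seen.

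CDC42, a GTPase that shapes the actin cytoskeleton (chromosome 1, 22052627 to 22092946, plus strand), was at 507 ± 129 CPM in obese asthma, 523 ± 196 in obesity without asthma, 472 ± 141 in healthy-weight asthma and 482 ± 142 at healthy weight without asthma. Its log2 fold changes for obese asthma were -0.01 ± 0.08, 0.11 ± 0.08 and 0.09 ± 0.08 against these 3 groups, all within the spread between children. RHOA (chromosome 3, 49359145 to 49412998, minus strand) was at 179 ± 60.0, 180 ± 63.0, 166 ± 44.9 and 173 ± 46.3 CPM in the same order, with log2 fold changes of -0.01, 0.09 and 0.03 (± 0.08 each). The first value of both genes was above 0 with RLE scaling and with DESeq2. Among regulators of helper subsets, the log2 fold changes for obese asthma against the same groups were 0.22, 0.61 and -0.23 for the Th1 factor TBX21 and 0.45, 0.21 and 0.16 for the regulatory factor FOXP3. GZMB had -0.86, 0.40 and -0.22, the glucocorticoid-induced FKBP5 -0.37, -0.43 and -0.10, and the NF-kB inhibitor NFKBIA 0.26, 0.29 and 0.23. None of these genes passed in edgeR. Against healthy weight without asthma, GATA3 was at 0.05 and CCR7 at -0.36. For GATA3 the values were 65.7 ± 15.4 CPM at healthy weight without asthma and 48.3 ± 10.0 in healthy-weight asthma.

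Ribosomal protein, T cell receptor signalling, PI3K and mTOR, erythrocyte, monocyte and B and plasma cell genes passed in none of the 6 contrasts with camera. In obese asthma against obesity without asthma their adjusted p values were 0.283, 0.901, 0.926, 0.489, 0.901 and 0.651. Of the 70 ribosomal protein genes 51 were lower, with a median of -0.02, and the PI3K and mTOR list held PIK3IP1, which passed when adjusted over the list alone. The glucocorticoid list did not pass there (adjusted p = 0.636), and its median of 0.06 and mean of 0.01 were above 0 while the test pointed to lower levels. In the lists that passed, median, mean and test had the same sign.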

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

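The tests of KLRB1 below were chosen after its result was seen, while the rule that singled out the samples was fixed before. In the interaction, the effect of asthma on KLRB1 in regulatory-like cells was 2.00 ± 0.28 higher on the log2 scale in obesity than at healthy weight. If memory cells miscounted as regulatory had carried the higher KLRB1 of obese asthma over obesity without asthma, the difference would shrink among cells with a FOXP3 UMI. It was 2.30 there (exact permutation p = 0.00217, n = 6) against 1.17 in the whole class, but the log value rests on few UMIs in obesity without asthma. In CPM the difference was 87.4 (120 ± 36.3 against 32.4 ± 26.4) and thus not smaller than the 84.0 of the class, which argues against memory cells. Within cluster 16, 1 of the 2 regulatory-like clusters, the difference was 1.06 (exact permutation p = 0.00217, n = 6, 233 ± 40.7 against 114 ± 30.5 CPM), which argues against the mix of clusters as the whole cause. Within cluster 6, the other, at a lower KLRB1 level, it was 0.52 (exact permutation p = 0.115, n = 6, higher in 5 of 6 wells), and whether the clusters differed was not tested. Each well held 1 child of every group, so free RNA of a well was shared by the groups and would not by itself set them apart. Free RNA would also raise naive-like cells alike, and these differed by 2.69 CPM (exact permutation p = 0.320, n = 6). With a source shared by the groups that comparison adds little. These causes were tested only against obesity without asthma, a comparison in which other splits of the children could not exclude chance. Against healthy weight without asthma KLRB1 in the class differed by 36.1 CPM (exact permutation p = 0.160). A difference of regulatory cells with obesity and asthma may be the source, but chance remains possible as well. The former is a hypothesis found and tested on the same children.

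The other results here are samples far from the 5 others of their group, in a test of 80 groups of samples over 20 measures that found 8. Chance gives about 1 in 20 groups, so some are what chance gives. At healthy weight without asthma the child of library 1 had 76.3% of cells in clusters of other types, against 5.14% to 10.1% in the others of its group and 2.48% to 28.7% in the other 23 children. Of the same child's cells 31.8% lay above the CD4 antibody threshold, against 92.1% to 97.8% in its group. Of all its cells 24.6% were B cells, 25.3% cytotoxic cells, 16.9% monocytes and 7.05% CD8 T cells. In obese asthma the child of library 2 had 2.10% proliferating-like cells, against 0.0941% to 0.618%, and 17.4% of its CD4 antibody-positive cells were in the cytotoxic cluster, against 0.246% to 6.57%. In obesity without asthma the child of library 1 had 5.79% cytotoxic cells among CD4 antibody-positive cells, against 0.611% to 2.13%. In healthy-weight asthma the child of library 2 had 31.8% memory-like cells, against 22.96% to 25.9%. In well 6 the CXCR3 antibody level, in centred log-ratio units, was -0.399 in the child at healthy weight without asthma, against 0.0119 to 0.158, and -0.412 in the obese child without asthma, against -0.0256 to 0.178. Both children shared this well, and levels were centred within library but not within well. A shift of the well was therefore not separated from a difference of these children.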

How the results depend on the processing

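The CD4 antibody threshold, the removal of the highest 10% of Scrublet scores, the omission of the child at healthy weight without asthma in library 1, and leaving out wells within classes are tests chosen after the results were seen. Wells are the replicates here, and for each result that changed with a setting the cause was not tested unless stated. Scrublet's own calls were not run as an alternative, since its automatic threshold called 0% of singlets in well 2 and 99.3% and 99.7% in wells 5 and 6. The denominator of shares was matched to the design after values had been seen. Precision was limited by the regulatory-like sums. In these, simulated changes of 1.5-fold were called for 50% of raised and 65% of lowered genes, against 87.5% and 82.5% in all CD4 cells. These rates hold for independently simulated genes with an average log2 CPM of at least 3.

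Class shares kept their direction in 246 recomputations and reversed in 14, and antibody levels kept theirs in 80 and reversed in 4. With the top-hashtag rule, which kept 33.7% of the singlets of well 2, the regulatory-like share differed by -0.539 points between obese and healthy-weight asthma. The same rule gave -0.0253 for proliferating-like cells in obese asthma against healthy weight without asthma, -0.686 for naive-like cells between the healthy-weight groups, -0.0769 for proliferating-like cells between the groups without asthma, and a log2 fold change of 0.0045 for RHOA against obesity without asthma. As log2 shares of antibody counts, CD25 differed by -0.058 and CD4 by 0.070 in obese asthma against obesity without asthma.

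Leaving out 1 well at a time gave these ranges for differences that changed sign. Proliferating-like cells ranged from -0.241 to 0.224 points in obese asthma against obesity without asthma, and regulatory-like cells from -0.139 to 3.04 against healthy-weight asthma. Against healthy weight without asthma the ranges were -10.8 to 2.42 for naive-like, -5.44 to 7.47 for memory-like and -0.128 to 0.312 for proliferating-like cells. For obesity without asthma against healthy weight they were -8.81 to 1.57 for memory-like and -0.289 to 1.11 for regulatory-like cells. In obese asthma against healthy weight without asthma the CD4 antibody difference reached -0.0275 and that of CXCR3 0.0031.

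Counts of called genes in all CD4 cells were alike in 102 recomputations and moved in 6, and those within classes were alike in 148 and moved in 32. With the well as block in place of library edgeR called 1 gene in all CD4 cells for obese against healthy-weight asthma and 1 for obesity without asthma. The same block gave 1, 2 and 3 genes in naive-like cells against healthy-weight asthma, for asthma at healthy weight and for obesity without asthma. In regulatory-like cells the block gave 0 against obesity without asthma, and 2 for asthma at healthy weight and 2 for the interaction, and it changed no other gene count by over 1.5 times. DESeq2 called 43, 4 and 3 genes in all CD4 cells against healthy-weight asthma, against healthy weight without asthma and in the interaction. In naive-like cells DESeq2 called 12 and 1 in the first and second of these contrasts, and in memory-like cells 1 against obesity without asthma. In regulatory-like cells it called 26 against healthy-weight asthma, 1 against healthy weight without asthma, 14 for asthma at healthy weight and 8 in the interaction. At resolution 0.5 edgeR called 1 gene in regulatory-like cells against healthy-weight asthma. Leaving out wells gave 0 to 3 genes in all CD4 cells against healthy-weight asthma, and 0 to 1 in naive-like cells against healthy weight without asthma. In regulatory-like cells the ranges were 0 to 2 against obesity without asthma, 0 to 5 against healthy-weight asthma, 0 to 2 against healthy weight without asthma, 0 to 3 for asthma at healthy weight, 0 to 2 for obesity without asthma and 0 to 1 for the interaction. Genes that edgeR called there without 1 well and not with all, named after their values were seen, were TOX2 against obesity without asthma without well 3, and GRIP1, RETREG1 and TTC3-AS1 against healthy-weight asthma without well 1 (TTC3-AS1 also without well 3). Against healthy weight without asthma they were SFMBT2 and TTC3-AS1 without well 3. Without well 4 SDAD1 and AC068279.2 were called for asthma at healthy weight. Without well 5 KLRB1 was called for asthma at healthy weight (-0.82) and for obesity without asthma (-0.84), along with low-level transcripts.

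List calls kept their side of the threshold in 257 recomputations, lost it in 186 and reversed in 1. The lists that passed with the preset correlation numbered 0 in each of the 6 contrasts with an estimated correlation and 0 with the directional fry test, and the mixed fry test gave 0 in 5 contrasts and 1 for asthma at healthy weight. With an estimated correlation their adjusted p values were 0.262, 0.722 or 0.884 against obesity without asthma, and 0.239, 0.264, 0.277, 0.279, 0.289 or 0.329 against healthy-weight asthma. They were 0.857 against healthy weight without asthma and 0.687 for obesity without asthma. For asthma at healthy weight they were 0.0752, 0.193, 0.214, 0.216, 0.226, 0.239, 0.284, 0.294, 0.308, 0.345, 0.371, 0.426 or 0.427, and for the interaction 0.212, 0.221, 0.256, 0.259, 0.293, 0.406, 0.475 or 0.657. With the directional fry test they were 0.536 or 0.878 against obesity without asthma, 0.206, 0.219, 0.261, 0.262, 0.287, 0.290, 0.297 or 0.328 against healthy-weight asthma, 0.844 against healthy weight without asthma and 0.948 for obesity without asthma. For asthma at healthy weight fry gave 0.142, 0.242, 0.268, 0.274, 0.328, 0.395, 0.414, 0.419, 0.467 or 0.505, and for the interaction 0.319, 0.349, 0.599 or 0.706.

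With RLE scaling the oxidative phosphorylation list had adjusted p = 0.0548 against obesity without asthma, and for obesity without asthma the Th1, Th2 and Th17 lists had 0.0574 and the glucocorticoid list 0.0540. With the well as block the Th2 list for obesity without asthma had 0.0582 and the heat shock list in the interaction 0.0511, and no other list lost its call with that block. For obesity without asthma 10 lists passed with the block, of which 9 also passed in the main fit. With the CD4 antibody threshold the lists against healthy weight without asthma had 0.225 (naive), 0.186 (follicular helper) and 0.111 (glucocorticoid). For asthma at healthy weight that threshold gave 0.0559 (mitochondrial), 0.0738 (chemotaxis and CD8) and 0.0635 (asthma association). For obesity without asthma it gave 0.152 (Th1), 0.0960 (Th2 and mitochondrial), 0.147 (Th17) and 0.0987 (glucocorticoid), and in the interaction 0.221 (heat shock) and 0.0810 (glucocorticoid). Other lists gained a call. In the order used for naive-like cells, 15, 17, 5, 17, 12 and 21 lists passed with that threshold. Of these 10, 15, 3, 13, 5 and 16 also passed in the main fit. With RLE scaling 10 lists passed against obesity without asthma (9 also in the main fit), 18 for asthma at healthy weight (17) and 7 for obesity without asthma (6).

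Without the child at healthy weight without asthma in library 1, the lists against that group had 0.0707 (follicular helper), 0.613 (interferon) and 0.199 (glucocorticoid). For asthma at healthy weight they had 0.0975 (asthma association), 0.342 (CD8), 0.213 (NK) and 0.0596 (platelet). For obesity without asthma 2 of the 10 lists still passed (interferon and oxidative phosphorylation) and 2 others did, and the 8 that were lost had 0.969 (cytotoxic, direction reversed), 0.661 (Th1), 0.240 (Th2 and mitochondrial), 0.256 (Th17), 0.127 (insulin and adipokine), 0.416 (glucocorticoid) and 0.456 (CD8). In the interaction they had 0.109 (glucocorticoid), 0.236 (CD8) and 0.149 (NK).

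Log2 fold changes of named genes were alike in 1551 recomputations, gained a call in 21, lost one in 14 and reversed in 30. In obese asthma against obesity without asthma, CDC42 and RHOA had 0.012 and 0.016 with DESeq2 and 0.012 and 0.016 with RLE scaling, while RHOA had 0.032 with all singlets kept, 0.0011 without the top Scrublet scores and 0.017 with the CD4 antibody threshold. Against healthy weight without asthma RHOA had -0.034 with all singlets kept. There the CD4 antibody threshold gave -0.079 for RHOA, 0.0087 for TBX21 and -0.039 for NFKBIA, the fit of only the compared groups 0.020 for GZMB, and the fit with no library term 0.053 for FKBP5. Without 1 well the ranges against obesity without asthma were -0.065 to 0.047 for CDC42, -0.036 to 0.026 for RHOA and -0.073 to 0.41 for TBX21. Against healthy-weight asthma they were -0.15 to 0.33 for FOXP3 and -0.13 to 0.72 for GZMB. Against healthy weight without asthma they were -0.014 to 0.060 for RHOA, -0.77 to 0.18 for TBX21, -0.12 to 0.21 for GATA3, -0.024 to 0.35 for FOXP3, -0.86 to 0.64 for GZMB and -0.29 to 0.069 for FKBP5.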

Other observations

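The tests in this part, other than the splits of the children, were chosen after the results were seen. Within memory-like cells, follicular helper genes were lower in obese asthma than in obesity without asthma for 9 of 11 genes. PDCD1, which encodes PD-1, had a log2 fold change of -1.38 ± 0.27, IL21, the follicular helper cytokine, -1.49 ± 0.49, TOX2 -0.81 ± 0.31 and the B-cell-follicle receptor CXCR5 -0.43 ± 0.18. PDCD1 and IL21 passed when adjusted over the list alone, and the camera test gave adjusted p = 2.83e-08 with the preset and adjusted p = 0.00683 with an estimated correlation.

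Th17 genes were lower in asthma than without at healthy weight in memory-like cells for 13 of 13 genes, with CCL20 at -1.64 ± 0.52 and ABCB1 at -0.70 ± 0.24 (camera adjusted p = 1.96e-07, and adjusted p = 0.0217 with an estimated correlation). In regulatory-like cells they were lower for 9 of 10 genes, with KLRB1 at -0.78, BATF at -0.94 ± 0.27 and CTSH at -0.97 ± 0.35. There 7 passed when adjusted over the list alone (camera adjusted p = 6.42e-08, and adjusted p = 0.0146 with an estimated correlation). In the interaction of obesity and asthma, Th17 genes in regulatory-like cells were more positive for 7 of 10 genes, with KLRB1 at 2.00, RORA at 0.54 ± 0.18 and STAT3 at 0.46 ± 0.18 (adjusted p = 3.89e-06, and adjusted p = 0.0412 with an estimated correlation). Asthma association genes were more positive for 12 of 16 genes there, with GATA3 at 0.97 ± 0.25 (adjusted p = 4.59e-04, and adjusted p = 0.0457 with an estimated correlation). These 5 were the list results within classes that passed with an estimated correlation, and naive-like cells had 0. Adjustment was over the 30 lists of each class and contrast, not over the 6 contrasts or the classes. Lists within classes were not tested in other splits of the children, so chance was not assessed. All but the follicular helper result involve the group at healthy weight without asthma. Its child of library 1, with a sample mostly of other cell types, gave only 66 regulatory-like cells. Values of these lists without that child are not given here.

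The lower interferon response of obese asthma against obesity without asthma was tested further. Without the child farthest from its group mean the list level differed by -0.23 (exact permutation p = 0.0281) against -0.31 with all children, which argues against 1 child as the whole cause. In naive-like cells alone it differed by -0.36 (exact permutation p = 0.00433, n = 6), which argues against the mix of cell classes. A difference in recent exposure to virus between the children was not tested and may also be a source.

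Other splits of the children within libraries were fitted in the same way, with 30 splits in all CD4, naive-like and memory-like cells and 50 in regulatory-like cells, the real one included. For genes in all CD4 cells and in naive-like and memory-like cells the real counts were 0. In each of the 6 contrasts 30 of 30 splits then gave as many by construction, which says nothing about chance. The highest other counts, in the order used for naive-like cells in the report, were 1, 1, 76, 1, 4 and 0 in all CD4 cells. They were 2, 2, 1, 1, 0 and 1 in naive-like cells and 2, 1, 5, 0, 2 and 2 in memory-like cells. Genes at an unadjusted p below 0.05 in all CD4 cells numbered 621, 1628, 1075, 1299, 619 and 1221 in the real split. The highest other counts were 2205, 2812, 3520, 2503, 2964 and 2877. In regulatory-like cells as many genes were called in 1 of 50 splits for obese asthma against healthy-weight asthma (real 2, highest other 1) and in 2 of 50 for the interaction (real 1, highest other 1). This excludes chance only within the splits of each contrast. Over the 5 contrasts of 2 groups, 7 of 245 values from the 49 other splits were 2 or more, in 5 splits and up to 22, and 20 values were 1 or more, in 14 splits. It could not be excluded against obesity without asthma, where 4 of 50 splits gave as many (real 1, highest other 2). In the 3 contrasts with a real count of 0, 50 of 50 splits gave as many by construction (highest others 22, 3 and 3). The counts of 76 and 22 genes, both against healthy weight without asthma, came from single splits. They may point to a structure of the samples other than the groups, which was not tested.

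For gene lists in all CD4 cells, chance could be excluded in none of the contrasts. The number of 30 splits with as many lists was 14 against obesity without asthma (real 10, highest other 16), 5 against healthy-weight asthma (real 15, highest other 18) and 26 against healthy weight without asthma (real 6, highest other 21). It was 4 for asthma at healthy weight (real 17, highest other 19), 12 for obesity without asthma (real 10, highest other 19) and 2 for the interaction (real 18, highest other 19). For the interferon list alone, in obese asthma against obesity without asthma, the real split had the smallest camera p of the 30, 6.96e-16 against 6.67e-11. Over the 5 contrasts of 2 groups, however, 7 of 145 values from the 29 other splits were as small, down to 8.73e-28, in 5 splits. The camera p of this list is therefore within what chance groupings gave.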
